A study of Homo sapiens with 8 samples.

How the data were processed

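RNA sequencing of the small cell lung cancer (SCLC) cell lines H128 and H146 was described by 8 sample labels, each a group of its own with 1 library. H128 cells received a control siRNA (siCont) or 1 of 2 siRNAs against RXRG (siRXRG2 and siRXRG3), or the compound HX531 at 5 or 10 µM, for 48 h, and 1 H128 library without the compound was the control of the HX531 libraries. These 6 libraries were analysed in 2 tables of 3 libraries each. Folds were computed only within a table, and levels given side by side across tables come from separate normalizations. The 2 libraries of H146 cells and of H146 cells that overexpress RXRG were not analysed here. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase, made into libraries with a directional kit and sequenced in pairs.

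The authors deposited FPKM values (fragments scaled to transcript length and to the mapped fragments of the library), which are named as such in the header of the table with the HX531 libraries. The header of the siRNA table names its values only as expression. Over 5893 genes at 10 FPKM or more in both controls, the estimated count per unit of value differed between the tables by a constant factor (median 1.02, 5th to 95th percentile 0.989 to 1.06), so those values were read as FPKM. The deposited estimated counts are expected counts that need not be whole, and 52.2% to 54.1% of them were whole to within 1e-06. The authors' deposited log2 fold columns equal the log2 ratio of FPKM with 0.01 in place of 0, with 0 differences over the same tolerance. Their deposited adjusted p-values come from a Poisson test, per the file headers, which compares the reads of 2 libraries and not the conditions. The submitters' processing notes name TopHat2, HTSeq and DESeq2 and the builds GRCh38, hg19 and hg38 without saying which was used where. Coordinates are given as in the tables, whose chromosome accessions are those of GRCh38. A further 3 TPM columns were not used. All genes listed (16829 in the siRNA table and 17069 in the HX531 table) are of the coding type. Whether the counting used strand, or how it divided reads between similar genes, is not given in the sources used here.

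The main measure was log2((FPKM + 1) / (control FPKM + 1)), which understates differences of genes at low levels, over genes with a mean of at least 1 FPKM in the 3 libraries of a table. A gene was counted as different at 2-fold or more in the same direction with both siRNAs or at both doses. Because each group held 1 library, no p-value was attached to these folds. Ratios of single genes carry 95% exact binomial intervals of the reads, which cover counting error only. Total estimated counts ran from 17635307 to 19666097 per library, and 3 reads corresponded to 0.0512 to 0.0576 FPKM at the median gene.

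The design, the alternatives, the naming rule and 31 gene lists were fixed before the data were examined. Named genes were RXRG, then the 8 highest and the 8 lowest genes of each comparison with a gene symbol and a mean of at least 5 FPKM, ranked by the smaller of the 2 absolute log2 folds where both had the same sign. Up to 4 members per list and 10 genes over all 4 contrasts were named in the same way, and other genes in the text were chosen after their values were seen. A list was said to stand apart where its median log2 fold lay at or below percentile 2.5, or at or above percentile 97.5, of 10000 random lists matched on deciles of mean level in both contrasts. The percentile describes these libraries and is not a p-value, and it was given for lists with at least 5 members past the floor, a minimum set after seeing the data.

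Alternatives changed the pseudocount, the floor, the fold threshold or the scaling (centring on the median of all genes, or TMM), or used counts with TMM, single arms, or limma with the 2 arms taken as replicates. An edgeR quasi-likelihood fit of the same kind on estimated counts rounded to whole numbers, a count without genes listed at 0 in the control or read-through genes, the hallmark sets annotated in the tables and a reduced ATF4 list were added after seeing the data. Some of the hallmark sets are not reported here. Both fits assume that the lone control varies like the 2 arms. Contrasts that share a control were compared with 100 simulations of unchanged libraries. The noise in these simulations came either from counting or from the difference between the 2 arms. The latter includes any real difference between the 2 siRNAs or the 2 doses. GC content and length came from the longest protein-coding transcript in GENCODE 29 and covered 98.9% and 98.7% of the genes past the floor. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and edgeR 4.0.16 were used.

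The methods were also tested on simulated data. The simulated counts had a dispersion (spread between libraries) of 0.02 and the same change in both arms. Between the real siRNA arms 199 genes differed 2-fold, so the simulated numbers of unchanged genes called can be too low for the real data. The recovered shares can be too high, because differences between the arms enter the error of the fits. In the real siRNA data limma did not call RXRG, which was at 8.82% and 8.20% of control. With 200 genes changed 4-fold among 11101 genes of the siRNA table, the 2-fold rule recovered 92.0% and called 0 unchanged genes. Among 11576 genes of the HX531 table it recovered 93.0% and called 0. The limma fit recovered 99.5% and 98.5% and called 1 and 13 unchanged genes in the siRNA and HX531 tables, and edgeR recovered 99.5% and 99.0% and called 2 and 12. Of 200 random lists of 25 genes, 6.5% in the siRNA table and 3.0% in the HX531 table lay outside the percentile limits in 1 contrast, against 98.5% and 100% after a log2 shift of 0.3. Random lists were ranked against random lists here, so the shares without a shift follow from the limits themselves. Members of a real list can vary together, so these shares can be too low for real lists.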

Results

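Transcript levels were measured in H128, a human small cell lung cancer cell line, after knockdown of RXRG or exposure to HX531 for 48 h. RXRG encodes the retinoid X receptor gamma, a nuclear receptor that binds DNA with partner receptors, and HX531 is known as an antagonist of retinoid X receptors. The title of the series names this receptor as a therapeutic target, and the comparisons ask which transcripts differ when it is depleted or when cells are exposed to the compound. Each group held 1 library, so no difference has a replicate check. Total estimated counts were 18007746 for siCont, 18072020 for siRXRG2 and 17670542 for siRXRG3, and 17648387, 17635307 and 19666097 at 0, 5 and 10 µM HX531. The 10 genes with most reads took 4.86% to 5.64% of a library.

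RXRG (chromosome 1, 165400922 to 165462416, minus strand) stood at 20.7 FPKM with the control siRNA, 1.83 FPKM with siRXRG2 and 1.70 FPKM with siRXRG3. These levels were 8.82% (95% counting interval 6.82 to 11.3) and 8.20% (6.28 to 10.5) of control, from 806, 71 and 66 reads. HX531 libraries also had lower RXRG, at 14.7 FPKM with 5 µM and 5.23 FPKM with 10 µM against 22.1 FPKM without compound. The remaining shares were 66.4% (59.6 to 73.9) and 23.7% (20.3 to 27.4). RXRA, another retinoid X receptor, was at 12.9, 9.83 and 10.6 FPKM in the siRNA libraries, and at 13.8, 13.7 and 8.07 FPKM with 0, 5 and 10 µM HX531. The list of RXR and partner receptors as a whole did not stand apart in either experiment.

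**Figure D1:**
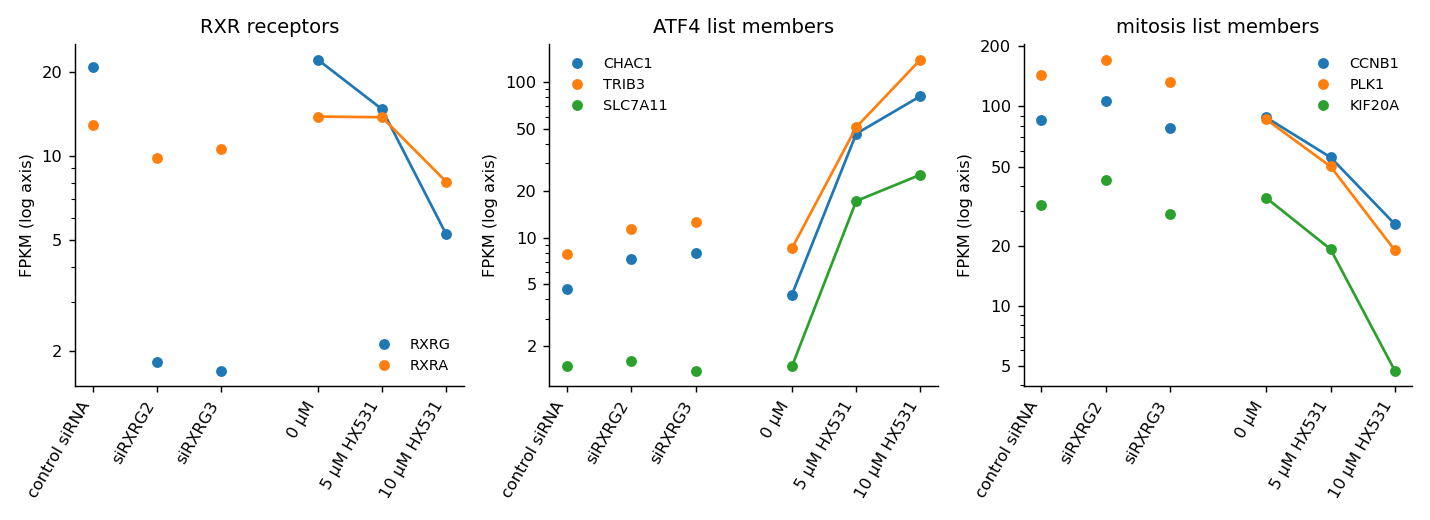
FPKM (log axis) of RXRG and RXRA (left), CHAC1, TRIB3 and SLC7A11 (middle), and CCNB1, PLK1 and KIF20A (right) in each of the 6 libraries, 1 point per library, with lines joining the HX531 doses. RXRG is at 1.83 and 1.70 FPKM with the siRNAs, CHAC1 is at 46.6 and 81.5 FPKM with HX531 against 4.29 without, and KIF20A is at 19.3 and 4.75 FPKM against 34.8.

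Besides RXRG, knockdown libraries shared lower levels of a small group of genes. S100A2, a calcium-binding protein, was at 24.4 FPKM in the control and 9.87 and 10.4 FPKM with siRXRG2 and siRXRG3, ratios of 0.405 (95% counting interval 0.337 to 0.486) and 0.427 (0.355 to 0.511). E2F7, a repressor of the E2F family, was at 18.1, 7.65 and 7.45 FPKM. TDG, a DNA glycosylase that removes mismatched thymine, was at 29.8, 13.9 and 9.88 FPKM. The placental growth factor gene PGF was at 28.4, 7.02 and 15.2 FPKM, and LITAF at 86.1, 47.1 and 44.7 FPKM.

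Among 11101 genes past the floor, 9 differed by 2-fold or more in the same direction with both siRNAs, 3 higher and 6 lower. Lower genes were RXRG, S100A2, E2F7, TDG, PLEKHA6 (6.33, 1.30 and 2.17 FPKM) and the read-through gene TNFAIP8L2-SCNM1. All 3 higher genes are uncertain. EIF3CL and the read-through gene ABHD14A-ACY1 were listed at 0 in the control, and EIF3CL and SMIM11A have near-identical copies among which reads can be divided. Without genes listed at 0 in the control and read-through genes, a count added after seeing the data, 1 gene was higher and 5 were lower. Taken alone, siRXRG2 gave 62 higher and 75 lower genes and siRXRG3 gave 13 and 53, while 199 genes differed 2-fold between the 2 siRNAs. After median centring the siRXRG2 split was 41 higher and 95 lower. A limma fit with both siRNAs as replicates called 0 genes at an adjusted p under 0.05 (163 at an unadjusted p under 0.05). The edgeR quasi-likelihood fit called 1, RXRG (adjusted p = 0.00892; 215 genes unadjusted).

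The other genes named by rank were REEP3 (8.35, 3.90 and 3.66 FPKM) and BTBD17 (10.7, 5.35 and 4.41 FPKM) on the lower side. Higher levels were seen for PGPEP1 (2.68, 5.95 and 6.90 FPKM), C11orf71 (4.91, 10.02 and 10.98 FPKM), TMEFF2 (3.39, 6.86 and 6.87 FPKM), RAB3IP (3.25, 6.57 and 7.05 FPKM), PARD6A (10.7, 19.7 and 20.1 FPKM) and TAF12 (12.5, 25.9 and 22.2 FPKM). The read-through gene NEDD8-MDP1 was at 2.84, 6.37 and 6.83 FPKM. MAGEA2B was at 11.12, 22.03 and 29.44 FPKM, but its near-identical copy MAGEA2 was at 26.04, 13.96 and 12.88 FPKM. The copies share 96.4% and 96.2% of their 50-base stretches, and their summed reads were 1288, 1264 and 1381, so their separate levels are uncertain.

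Of the 31 lists, 6 had too few members past the floor for a percentile, and cholesterol synthesis was the only one of the others to stand apart with both siRNAs. Its median log2 fold was −0.21 with siRXRG2 (percentile 0.01) and −0.08 with siRXRG3 (percentile 0.39), with 12 of 24 members lower and 4 higher in both. HMGCS1, an early enzyme of the pathway, was at 71.5, 30.1 and 41.1 FPKM. HSD17B7 was at 42.9, 29.6 and 28.8 FPKM and INSIG1 at 59.8, 44.5 and 43.5 FPKM, while PMVK was higher (31.1, 37.7 and 45.6 FPKM). The larger hallmark set of cholesterol homeostasis, added after seeing the data, did not stand apart, with medians of 0.04 (percentile 28.7) and 0.04 (percentile 45.5). Several other lists lay past a limit only with siRXRG2 or only with siRXRG3. On the lower side these included Wnt pathway targets (percentile 0.06 with siRXRG2) and fatty acid synthesis (percentile 0.36 with siRXRG3). Both contrasts share the control library, so the position of the cholesterol synthesis list may come from the control.

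Cell cycle lists differed between the siRNAs. The mitosis list had a median of 0.31 with siRXRG2 (percentile 100) and −0.11 with siRXRG3 (percentile 0.03). The S phase and replication list had 0.26 (percentile 100) and 0.02 (percentile 14.2). For the ATF4 and unfolded protein response list the medians were 0.05 (percentile 41.6) and 0.26 (percentile 99.99). Its members DDIT3 (13.98, 23.23 and 24.83 FPKM), CHAC1 (4.64, 7.23 and 7.99 FPKM), TRIB3 (7.87, 11.4 and 12.6 FPKM) and CRELD2 (15.6, 23.4 and 22.4 FPKM) were higher with both. Neuroendocrine markers had medians of −0.05 (percentile 5.07) and 0.18 (percentile 98.3).

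Relative to the median of all genes, the remaining lists had these median log2 folds with siRXRG2 and siRXRG3. Fatty acid synthesis had −0.09 and −0.17, retinoid, LXR and PPAR targets −0.00 and 0.07, and RXR and partner receptors 0.04 and −0.14. Stem cell and pluripotency genes had −0.20 and −0.09, ABC transporters and drug response 0.16 and 0.00, the Notch pathway −0.06 and −0.13, and Wnt pathway targets −0.36 and −0.07. Replication-dependent histones had −0.11 and −0.14, p53 targets 0.01 and −0.18, DNA repair 0.13 and −0.02, and apoptosis regulators 0.01 and −0.15. Heat shock and oxidative stress had −0.01 and −0.03, hypoxia and glycolysis −0.06 and 0.04, interferon response −0.15 and −0.15, and antigen presentation −0.06 and −0.09. Epithelial-mesenchymal genes had −0.07 and −0.08, oxidative phosphorylation −0.01 and 0.15, cytosolic ribosomal proteins −0.02 and −0.06, MYC targets and ribosome biogenesis 0.01 and −0.08, and immediate early genes −0.15 and −0.05. Too few members passed the floor for a percentile in the non-neuroendocrine SCLC (4 members), fibroblast (3), blood cell (2), endothelial (1) and non-malignant lung epithelial (0) lists, and 0 mitochondrially encoded genes are listed. The endothelial cadherin gene CDH5 was at 32.1, 8.65 and 17.4 FPKM.

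Folds of the 2 siRNAs correlated across genes, which are not independent replicates, with r = 0.29 and a covariance of 0.0282. Both contrasts share the control library, which alone gave a simulated r of 0.50 with either kind of noise. The r of 0.29 was lower and shows no agreement beyond the shared control. The simulated covariance was 0.00393 with counting noise and 0.0689 with noise as large as the difference between the 2 siRNA libraries. In the latter simulation 33.8 genes on average passed 2-fold in both, against 9 observed, and independent lists would share 0.0726 higher and 0.358 lower genes. At that larger noise, which includes any real difference between the siRNAs, the shared control alone gave more overlap than was observed. A control of 1 library cannot be split, so part or all of the overlap beyond RXRG may come from the control. Between the controls of the siRNA and HX531 tables, which were normalized separately, RXRG was at 20.7 and 22.1 FPKM, but S100A2 was at 24.4 and 78.1 FPKM and CDH5 at 32.1 and 13.5 FPKM.

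HX531 libraries had higher levels of 22 of 29 members of the ATF4 and unfolded protein response list at both doses, and 7 were lower. Its member CHAC1, a glutathione-degrading enzyme, was at 4.29, 46.6 and 81.5 FPKM with 0, 5 and 10 µM, ratios of 10.9 (95% counting interval 9.02 to 13.2) and 19.0 (15.84 to 22.96). The inhibin beta E gene INHBE was at 2.60, 49.3 and 89.1 FPKM, the cystine transporter gene SLC7A11 at 1.48, 17.2 and 25.4 FPKM, and TRIB3 at 8.53, 51.4 and 140.2 FPKM. Lower levels were seen for the lipogenic regulator SREBF1 (21.01, 6.96 and 4.35 FPKM), the fatty acid binding protein gene FABP3 (766, 324 and 80.7 FPKM) and S100A2 (78.1, 25.1 and 4.91 FPKM). Mitotic genes were lower at both doses and further from control at 10 µM.

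Of 11576 genes past the floor, 140 differed by 2-fold or more at both doses, 114 higher and 26 lower. At 10 µM, 106 of the 114 and 24 of the 26 were further from control than at 5 µM. The 5 µM library alone gave 121 higher and 31 lower genes, and the 10 µM library 769 and 430. The median log2 fold of all genes was 0.03 at 5 µM and 0.12 at 10 µM, and after centring on it the 10 µM split was 574 higher and 584 lower. With both doses taken as replicates, limma called 3 genes at an adjusted p under 0.05 (CHAC1, INHBE and SLC7A11; 783 at an unadjusted p under 0.05) and edgeR called 0 (637 unadjusted).

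**Figure D2:**
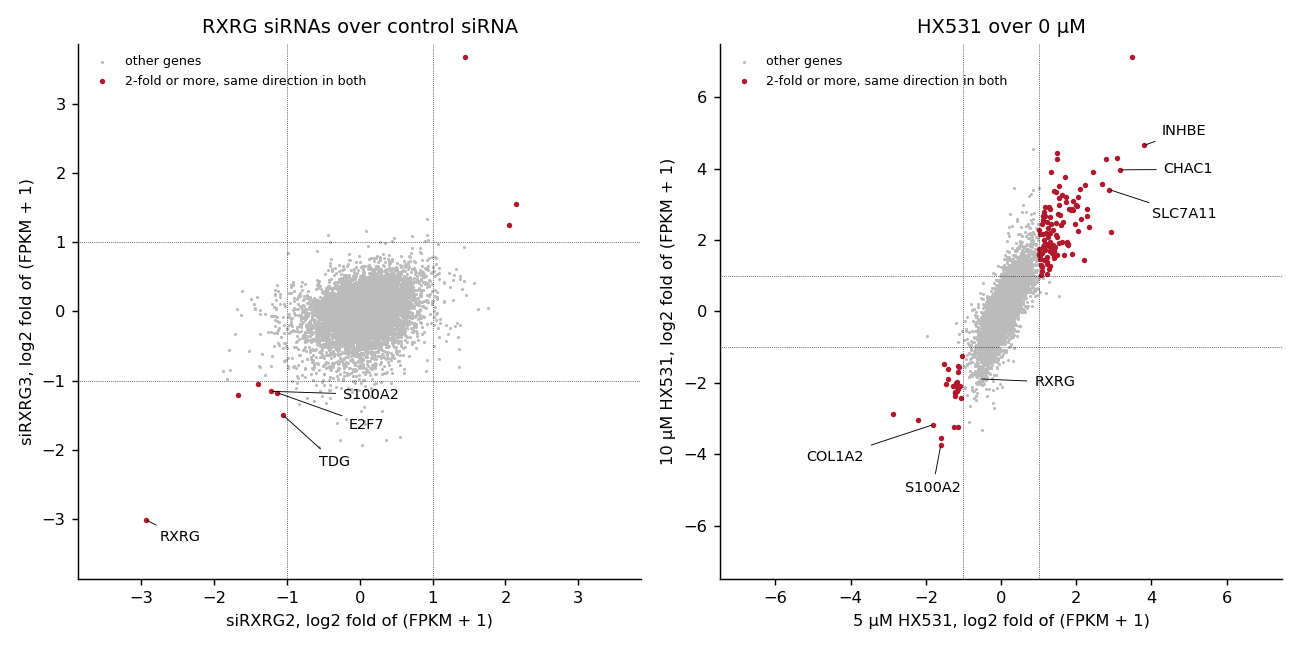
Log2 fold of (FPKM + 1) of each gene in the 2 siRNA libraries (left) and at 5 and 10 µM HX531 (right), each against its control library, with dotted lines at 2-fold. Red points mark the 9 and 140 genes at 2-fold or more in the same direction on both axes.

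The remaining higher genes named by rank were LARP6 (8.02, 74.9 and 174.5 FPKM), ADM2 (1.83, 17.2 and 32.6 FPKM), GDF15, a stress-induced cytokine gene (0.49, 9.23 and 27.5 FPKM), and BEX2 (0.07, 10.9 and 148.8 FPKM). BEX2 had 1 read in the control, so that its ratio at 5 µM was 156 with a counting interval of 27.7 to 6203. Lower genes were the collagen gene COL1A2 (16.0, 3.84 and 0.88 FPKM), HEPACAM2 (15.7, 4.54 and 0.42 FPKM), PDE1A (10.9, 3.12 and 3.25 FPKM), SHF (17.1, 5.81 and 4.89 FPKM) and ANKRD65 (18.8, 7.57 and 3.64 FPKM).

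The ATF4 and unfolded protein response list stood apart on the higher side, with medians of 1.29 at 5 µM and 1.70 at 10 µM (percentile 100 in both), or 1.58 at 10 µM relative to all genes. At both doses 16 of 29 members were 2-fold higher, among them VLDLR (1.13, 9.43 and 12.7 FPKM), the transcription factor gene ATF4 itself (274.9, 642.6 and 567.9 FPKM), DDIT3 (26.7, 129.0 and 321.7 FPKM) and ASNS, asparagine synthetase (119.1, 406.9 and 460.7 FPKM). The 7 members lower at both doses were HSPA5, HSP90B1, SDF2L1, CRELD2, MANF, PDIA4 and CALR. HSPA5, a chaperone of the endoplasmic reticulum, was at 244.7, 142.7 and 166.5 FPKM.

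Lists of dividing cells stood apart on the lower side. All 30 mitosis members were lower at both doses, with medians of −0.52 and −1.67 (percentile 0 in both, −1.79 at 10 µM relative to all genes), and 28 were 2-fold lower at 10 µM. KIF20A was at 34.8, 19.3 and 4.75 FPKM, PLK1 at 86.2, 50.1 and 19.0 FPKM, and MKI67 at 48.58, 29.04 and 9.57 FPKM. In the S phase and replication list 28 of 30 members were lower at both doses, with medians of −0.30 and −1.06 (−1.18 relative to all genes), and RRM2 was at 99.9, 59.9 and 17.9 FPKM. Replication-dependent histones had medians of −0.34 and −0.68 (−0.81 relative to all genes).

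Many lipid synthesis genes were lower too. At both doses 10 of 15 fatty acid synthesis members were lower and 4 higher, and 16 of 24 cholesterol synthesis members were lower and 3 higher. Fatty acid synthesis stood apart with medians of −0.21 and −0.43 (percentiles 0.39 and 0.25, −0.55 at 10 µM relative to all genes), and FASN, fatty acid synthase, was at 85.9, 55.7 and 33.4 FPKM. With a pseudocount of 5 its 5 µM median was −0.12 and no longer stood apart, and the hallmark set of fatty acid metabolism (−0.05 and −0.10, percentiles 8.70 and 1.89) did not stand apart. Cholesterol synthesis did not stand apart at both doses, with medians of −0.14 (percentile 4.27) and −0.91 (percentile 0, −1.03 relative to all genes). At 10 µM 9 of 24 members were 2-fold lower, such as ACAT2 (61.1, 34.3 and 18.5 FPKM). The hallmark set of cholesterol homeostasis did not stand apart either (−0.05 and −0.32, percentiles 9.99 and 0), with 8 members 2-fold higher and 15 lower at 10 µM. Hypoxia and glycolysis stood apart with −0.14 (percentile 2.28) and −0.34 (percentile 0.40, −0.46 relative to all genes), although VEGFA, an angiogenic growth factor gene, was higher (12.1, 46.5 and 93.0 FPKM). LDHA was at 866, 552 and 344 FPKM. That list no longer stood apart at a floor of 5 FPKM or a pseudocount of 5. Nor did the hallmark sets of hypoxia (0.03 and 0.06, percentiles 50.9 and 20.7) and glycolysis (−0.02 and 0.01, percentiles 13.02 and 8.38).

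Relative to the median of all genes, the other lists had these median log2 folds at 5 and 10 µM. RXR and partner receptors had −0.01 and −0.05, retinoid, LXR and PPAR targets −0.01 and −0.18, neuroendocrine markers 0.11 and −0.07, and stem cell and pluripotency genes −0.11 and −0.54. ABC transporters and drug response had −0.05 and −0.11, the Notch pathway −0.04 and −0.36, Wnt pathway targets 0.01 and −0.06, p53 targets −0.06 and 0.07, and DNA repair −0.07 and −0.46. Apoptosis regulators had 0.13 and 0.33, heat shock and oxidative stress −0.07 and −0.01, interferon response 0.05 and 0.24, and antigen presentation 0.15 and 0.13. Epithelial-mesenchymal genes had −0.04 and 0.06, oxidative phosphorylation −0.19 and −0.59, cytosolic ribosomal proteins 0.16 and −0.17, MYC targets and ribosome biogenesis −0.13 and −0.30, and immediate early genes −0.05 and 0.07. The median of the retinoid, LXR and PPAR targets hid a split. At 10 µM 3 of 11 members were 2-fold higher and 3 were 2-fold lower, and at 5 µM 0 and 1. The quartiles at 10 µM were −0.70 and 0.84 before centring. The lower members were SREBF1 as above, LPCAT3 (23.4 and 9.53 FPKM with 0 and 10 µM) and MYLIP (4.53 and 1.62 FPKM). The higher members were CPT1A (1.27 and 4.18 FPKM), PLIN2 (2 and 7.32 FPKM) and SMPDL3A (0.52 and 2.1 FPKM). The non-neuroendocrine SCLC (4 members), endothelial (1), non-malignant lung epithelial (1) and blood cell (0) lists were too small for a percentile. All 4 fibroblast markers past the floor were lower at both doses, with COL1A2 as above, FAP at 4.07, 1.17 and 0.06 FPKM, LUM at 2.81, 1.02 and 0.36 FPKM, and POSTN at 7.66, 3.62 and 0.71 FPKM. CDH5 was at 13.5, 8.16 and 2.64 FPKM.

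**Figure D3:**
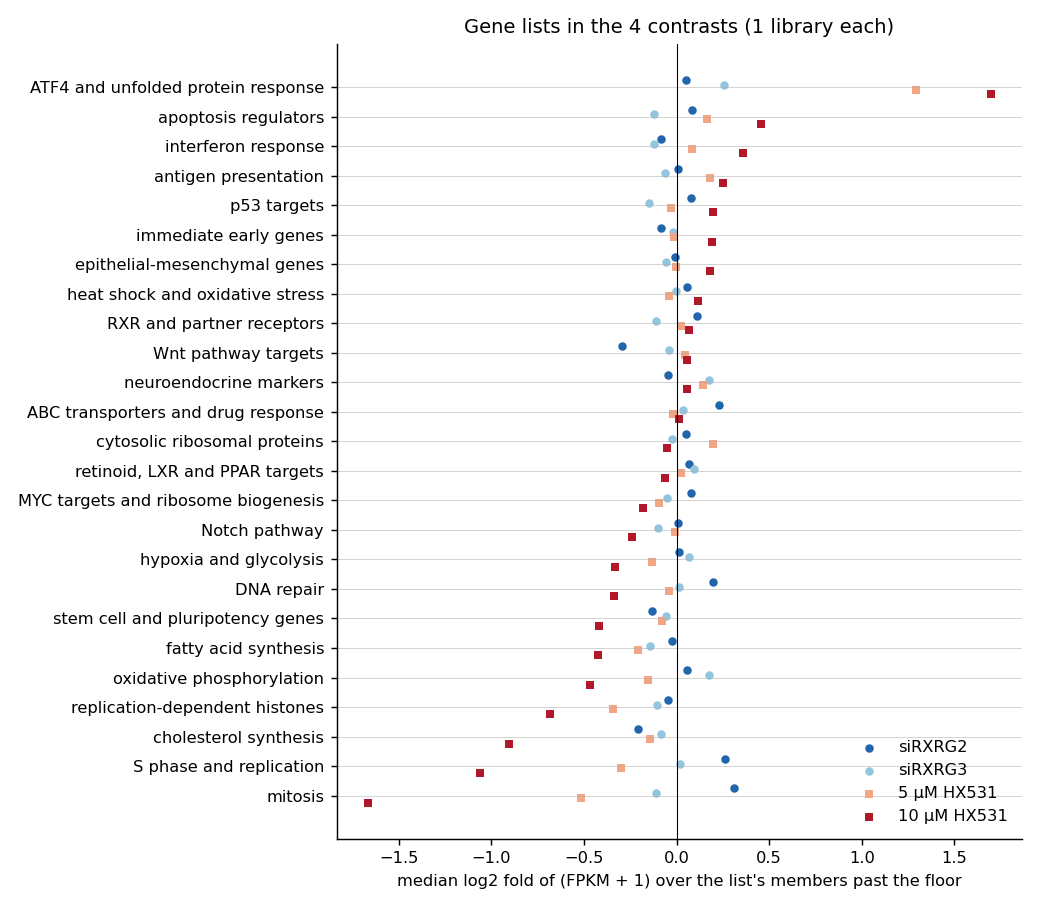
Median log2 fold of (FPKM + 1) of each gene list with at least 5 members past the floor, in the 4 contrasts, 1 library each against its control. The mitosis list lies at −1.67 and the ATF4 list at 1.70 with 10 µM HX531.

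Folds at 5 and 10 µM correlated across genes (r = 0.79, covariance 0.169). Unchanged simulated libraries sharing the control gave r = 0.51 with counting noise and 0.50 with noise as large as the difference between the doses. Their covariance was 0.0039 and 0.0975 with these kinds of noise. That second kind of noise includes any effect of dose itself, so it can overstate the noise of unchanged libraries. It gave 98.6 genes on average and at most 119 at 2-fold in both, against 140 observed and a mean of 0.01 with counting noise. Independent lists would share 8.04 higher and 1.15 lower genes. Here too part of the excess may come from the shared control.

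S100A2 was lower in all 4 contrasts and ranked first by smallest fold among shared genes at a mean of at least 5 FPKM. DDIT3, which encodes the stress-induced transcription factor CHOP, was higher in all 4, as were PGPEP1 (2.96, 5.81 and 19.05 FPKM at 0, 5 and 10 µM), IL10RB (5.19, 8.80 and 13.7 FPKM), PLGRKT and C11orf74. CDH5, HR, SNN (66.71, 29.54 and 13.96 FPKM) and AQP3 were lower in all 4. Among 11024 genes tested in both, 3 passed 2-fold in the same direction in all contrasts (S100A2 and the uncertain EIF3CL and SMIM11A), against 0.0292 for independent lists. At 1.5-fold, 19 genes were shared and 5 went opposite ways, against 2.498 expected to be shared. The expected number going opposite ways was not computed, so how much of the excess depends on direction is not shown. The 19 include the uncertain EIF3CL and SMIM11A and the read-through genes NEDD8-MDP1 and RPS10-NUDT3. Mean folds of the experiments, which have separate controls, correlated weakly across genes (Pearson r = 0.19, Spearman rho = 0.16).

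In the authors' deposited table, 7033 genes had an adjusted p under 0.05 for siRXRG2, 5605 for siRXRG3, 6165 for 5 µM and 10104 for 10 µM HX531. That test compares the reads of 2 libraries, not the conditions.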

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

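The test on GC content and length was chosen before its result was seen, and the comparison of the siRNA libraries with each other, chosen after, restates the difference and is given only as a value. The mitosis list drew attention because the siRNAs against the same gene placed it on opposite sides of the control, with a median log2 fold of 0.31 for siRXRG2 and −0.11 for siRXRG3. The difference has 1 library on each side and was not tested across replicates. Of 30 members, 28 were higher with siRXRG2 and 23 lower with siRXRG3. The quartiles of the members' log2 folds with siRXRG3 were −0.18 and −0.02. CCNA2 (40.2 FPKM in the control, 56.1 and 24.9 FPKM) and CENPA (15.8, 23.3 and 9.25 FPKM) lay below these quartiles and are not typical. With both siRNAs 6 members were higher, such as MKI67 (65.5, 74.8 and 73.9 FPKM).

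GC content and transcript length do not account for the difference, since the list median of siRXRG2 over siRXRG3 was 0.40 before and 0.43 after a fit on them and on level. RXRG levels were close, at 1.83 and 1.70 FPKM, and the effects of an siRNA on other targets, or of growth state at harvest, were not tested.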

How the results depend on the processing

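The edgeR fits, the counts without read-through genes and genes at 0 in the control, and the reduced ATF4 list were chosen after seeing the data, and the other alternatives before. Named genes were recomputed only with the other pseudocounts, a floor of 5 FPKM, centring and TMM scaling. No 2-fold value of a named gene changed sign, but none of these settings could reverse one. A pseudocount or floor cannot change a sign, and centring moved log2 folds by 0.12 or less. Of 490 list medians 46 changed sign, 0 of which had lain past a percentile limit, while 70 values of named genes and 19 list medians crossed their limit. Where a value moved, the cause was not tested. The 9 siRNA genes became 29 with a pseudocount of 0.1, 1 with 5, 4 at a floor of 5 FPKM, 24 from counts with TMM, 113 at 1.5-fold, 1 at 3-fold, 137 with siRXRG2 alone, 66 with siRXRG3 alone, 0 with limma and 1 with edgeR. The 140 HX531 genes became 310 and 66 with those pseudocounts, 301 from counts with TMM, 622 at 1.5-fold, 42 at 3-fold, 1199 with 10 µM alone, 3 with limma and 0 with edgeR. Removing the floor, centring, TMM scaling, protein-coding genes only (which removed 0 genes) and leaving out read-through genes and genes at 0 in the control kept both counts within 1.5 times. RXRG log2 folds of −2.94, −3.01 and −1.89 (siRXRG2, siRXRG3, 10 µM) became −1.91, −1.94 and −1.41 with a pseudocount of 5, and the siRNA values −3.43 and −3.53 with 0.1. The 3 shared genes became 19 at 1.5-fold, 1 at a floor of 5 and 8 with a pseudocount of 0.1. The correlation of knockdown and HX531 became 0.17 at that floor and 0.21 with that pseudocount, and that of the doses 0.80 at that floor. Stem cell and pluripotency genes stood apart with both siRNAs only at a floor of 5 (−0.34 and −0.27), and hypoxia and glycolysis had −0.14 at 5 µM there and −0.20 at 10 µM with a pseudocount of 5. ABC transporters and drug response went from 0.01 to −0.36 at 10 µM and from 0.23 to 0.05 with siRXRG2 at a floor of 5. With 1 library per group, depth limits only the counting error. Without DDIT3, TRIB3, CHAC1 and SLC7A11 the ATF4 list had medians of 0.92 and 1.55 with HX531 and −0.01 and 0.25 with siRXRG2 and siRXRG3 (0.05 and 0.26 with all members). Alternatives for the H146 libraries gave no value, because these were not analysed here. No paired analysis was possible because each group holds 1 library.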

Other observations

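The hallmark sets and the tests on library scaling and on lower RXRG were chosen after the result was seen, and the other tests before. Oxidative phosphorylation genes did not stand apart at both HX531 doses (percentiles 9.67 and 0.21), with 27 of 28 members lower at both doses and 28 lower at 10 µM. Of 21 heat shock and oxidative stress members, 9 were higher and 6 lower at both doses. HMOX1, which encodes heme oxygenase, was at 11.4, 23.8 and 136.1 FPKM with 0, 5 and 10 µM, and NQO1, a quinone reductase gene, at 8.87, 20.1 and 52.3 FPKM. The small heat shock protein gene HSPB1 was lower (562, 360 and 210 FPKM). Of 21 apoptosis regulators, 14 were higher and 4 lower at both doses, with HRK at 1.59, 5.18 and 9.88 FPKM, BBC3 at 1.31, 3.35 and 5.67 FPKM, PMAIP1 at 16.4, 30.5 and 42.2 FPKM, and BIRC5, an inhibitor of apoptosis also in the mitosis list, at 74.2, 43.7 and 15.1 FPKM. Neither of these lists stood apart at both doses. The hallmark set of apoptosis had medians of −0.01 and 0.02 (percentiles 27.6 and 25.4). SLC31A1, a copper transporter gene, was at 12.5, 21.3 and 44.1 FPKM.

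Of 20 neuroendocrine markers, 11 were higher and 7 lower at both doses, and the list did not stand apart. NCAM1 was at 56.4, 92.5 and 165.4 FPKM with 0, 5 and 10 µM HX531, SEZ6 at 19.4, 28.8 and 48.0 FPKM and UCHL1 at 721, 949 and 1350 FPKM, while NEUROD1, a neuronal transcription factor gene, was at 126, 97.1 and 42.2 FPKM and SYN1 at 35.5, 29.9 and 25.5 FPKM. PPARG, a partner receptor of RXR, was at 0.18, 0.27 and 2.01 FPKM. Of 50 hallmark sets annotated in the tables, the unfolded protein response stood apart on the higher side with HX531 (medians 0.05 and 0.22, percentiles 99.5 and 100). Hallmark medians are not centred, and the median of all genes was 0.03 at 5 µM and 0.12 at 10 µM, so this shift was small. The 7 on the lower side included E2F targets (−0.21 and −0.62), the G2M checkpoint (−0.22 and −0.54), MYC targets v1 (−0.17 and −0.33) and oxidative phosphorylation (−0.12 and −0.32), besides DNA repair and the mitotic spindle. With the siRNAs, fatty acid metabolism stood apart on the higher side (0.17 and 0.12, against 0.07 and 0.03 for all genes). The sets on the lower side included androgen response and apical junction.

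The higher ATF4 list with HX531 is not a matter of library scaling, as the smaller of its medians was 1.26 after centring each library on all genes. It is not accounted for by GC content or transcript length, with 1.37 after a fit on them and on level. Lower RXRG transcript did not come with a rise of that size in the siRNA libraries. There RXRG was at a lower share of its own control than at either dose, and the list medians were 0.05 and 0.26. With 1 library per siRNA and a separate control, these values cannot exclude a contribution of lower RXRG. Blocked receptor protein, effects of HX531 that bypass the receptor and differences between single cultures stay open and were not tested.

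The weak correlation of knockdown and HX531 folds across genes was 0.20 for residuals after a fit on GC content, transcript length and level, against 0.19 before. Without 100 members of the mitosis, S phase, histone and ATF4 lists it was 0.19. These trends and the members of these lists therefore do not make up the correlation. Only 100 of 11024 genes were removed, so wider cell cycle or stress responses beyond these lists were not tested. Shared effects of lower RXRG and general responses of stressed cells remain open and were not tested.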
